A study of Mus musculus with 4 samples.

How the data were processed

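The 4 groups of sorted γδ T cells were measured by droplet single-cell RNA sequencing, with 1 library each of adult spleen, pup spleen, adult meninges and pup meninges. The deposited tables hold counts: raw UMI counts per gene symbol and cell barcode, whole numbers with no scaling. The submitters' processing notes name bcl2fastq, Cell Ranger and the mm10 build. Their versions, the annotation, the chemistry and the way barcodes were called as cells are not given in the sources used here. The combined deposited table held the same barcodes as the 4 tables per library, differed from them in 0 values and was not used. The tables list 31053 genes. Punctuation lost from 2412 symbols was restored, and 30464 symbols matched a table of current mouse gene symbols.

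Barcodes were kept with at least 200 and at most 6000 detected genes and at most 10% mitochondrial UMIs, which kept 1864 of 2296. In the order adult spleen, pup spleen, adult meninges and pup meninges, 198, 24, 11 and 20 barcodes had too few genes, 46, 152, 19 and 5 too many mitochondrial UMIs, and 1 pup meningeal barcode too many genes. Scrublet, as run in scanpy, called 11, 11, 2 and 9 kept cells as doublets, and these were kept. For clustering, counts were scaled to 10000 per cell and log transformed, and 2000 variable genes were taken without receptor, immunoglobulin, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes. The Leiden method was run on 20 principal components and 15 neighbours at resolution 0.8, all libraries together with no batch correction, and gave 12 clusters.

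Clusters were named from 16 marker lists of cell classes. A cluster was given the class whose markers were found in the highest mean share of its cells, if at least 3 of them were each found in at least 25% of cells. It stayed unnamed if its median depth was over 3-fold below that of the library with most of its cells and none of its 10 leading genes was a marker of that class. Clusters 7 and 8 were B-like, and cluster 11 stayed unnamed for its low depth. The nearest class of cluster 11 was also γδ T cells, with 10 of 13 markers each found in at least 25% of cells, at a median of 1481.5 UMIs. Cluster 0, with 7 of 13 at 613 UMIs, passed, as depth was judged against the library with most of its cells. The 9 other clusters, all nearest to γδ T cells, stayed numbered and held 1640 cells. For each library, the UMIs of these cells were summed, to 1507714, 6794037, 903670 and 1149587 UMIs, and scaled to the library total (CPM). The floor of 3 UMIs over a summed library stands at 1.99, 0.442, 3.32 and 2.61 CPM, and a fold against 0 UMIs was computed against it. Such a fold leaves out the counting error of the other library, so the lower bound of the exact interval is given beside it.

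The 4 comparisons are adult meninges over adult spleen, pup meninges over pup spleen, pup meninges over adult meninges and pup spleen over adult spleen. With 1 library per group no test was run, and no p-value or count of changed genes is given. Each ratio carries the exact conditional binomial (Clopper-Pearson) 95% interval of its counts, and shares carry the Clopper-Pearson interval. For a share of 0, the limit of 3 cells of the total and the upper bound of the exact interval are both given. The 16 gene lists were the type 17, type 1, naive and recirculating, tissue residence, cell cycle, fetal and immature, activation and checkpoint, cytokine, chemotactic receptor, neural receptor, lipid, glycolysis, interferon response, stress, T cell receptor and sex-linked lists. A list is given as its median log2 ratio, with 0.5 added to each count, over members with at least 10 UMIs in both libraries together. Its percentile is that among 10000 random lists of the same size, matched on expression in 20 bins. Its interval comes from 1000 Poisson draws of the counts. Members at least 2-fold higher, at least 2-fold lower and between are counted as a rule of size.

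Named genes were the 10 with the largest ratio at the interval bound nearest to no difference in each direction, among genes with at least 30 UMIs. To these were added genes fixed beforehand, among them Il17a, Il17f, Il23r, Il1r1, Cxcr6, Ifng, Tbx21, Cd27, S1pr1 and Mki67, leading and opposing members of each list, and receptor and sex-linked genes. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, sex-linked and Gm- or Rik-numbered genes outside the lists were left out of the ranking. The groups, comparisons, filters, marker and gene lists, naming rule and 11 alternatives for lists and genes were fixed before the data were examined. Alternatives covered scaling (TMM and median of ratios), equal weight per cell, the cells used, the mitochondrial limit, doublets, the added count, the minimum of UMIs, cycling cells, the clustering resolution (0.4 and 1.5), thinning, and V gene use per cell instead of per UMI. A further 4 alternatives for lists and genes, and thinning to 2000 UMIs, were added after the data had been seen.

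The procedure was tested on simulated data, in which summed libraries were drawn from Poisson distributions with 200 genes changed by a known ratio per comparison. Filtering and clustering were not part of this test, and neither were differences between cells, as the draws follow the model behind the intervals. Intervals covered the true ratio for 96.1% to 97.0% of unchanged genes. The interval excluded no difference for 83.3, 94.8, 96.7 and 100% of genes changed 4-fold, in the order of adult tissue, pup tissue, age in meninges and age in spleen. For genes changed 1.5-fold it did so for 35.3, 45.6, 38.2 and 58.8%. The 2-fold rule was passed by 34.7, 55.7, 54.2 and 48.6% of genes changed 2-fold. In either direction it was passed by 6.43, 7.42, 5.84 and 5.57% of unchanged genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2 and igraph 0.11.9 were used, with R 4.3.3 and edgeR 4.0.16 for the TMM factors.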

Results

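Single-cell RNA counts were collected from γδ T cells, sorted as CD45+ TCRβ− TCRγδ+ cells from the spleen and the meninges of naive C57BL/6 mice. Adults were 8 weeks old and male, and pups were at postnatal day 7 with their sex listed as unknown. Each of the 4 groups was a single 10x Chromium library, pooled from 15 animals for meninges and from 5 for spleen, so there were no replicates. The adult spleen library held 1101 barcodes and 1964461 UMIs, the pup spleen library 854 and 7327405, the adult meninges library 206 and 976238, and the pup meninges library 135 and 1514801. After filtering, 889, 687, 178 and 110 cells remained in the same order, with medians of 984, 8679, 5175 and 12672.5 UMIs per cell. All intervals are 95% intervals and cover counting error only, not the difference between animals or between sorts. Those of ratios, summed counts, list medians and V gene shares treat each UMI as independent, so differences between the cells of a library are left out too. Sex goes with age in this design, and the number of animals pooled goes with tissue.

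Most sorted cells carried γδ T cell transcripts. Clusters 0 to 6, 9 and 10 met the marker rule for γδ T cells and held 749 cells of adult spleen, 645 of pup spleen, 169 of adult meninges and 77 of pup meninges. Every comparison sums over all of these clusters. The markers of that rule include genes of T cells at large, such as Cd3e, Cd3d and Cd3g, so the rule alone does not tell γδ from αβ T cells. Adult spleen cells lay mostly in clusters 0 (501 cells) and 1 (175), and pup spleen cells in clusters 2 (204), 3 (145), 4 (132) and 6 (98). Adult meningeal cells lay in clusters 5 (115), 1 (31) and 3 (16), and 58 of the pup meningeal cells lay in cluster 9. Among the 10 leading genes of clusters 2, 3 and 10 stood markers of other classes, namely Cd8b1 (αβ T cells), Tyrobp and Klrb1c (NK cells), and Car2 (erythroid cells). At least 1 UMI of Trdc, the constant segment of the δ chain, was found in 98.2%, 98.8% and 100% of the cells of these 3 clusters, at median depths of 7137.5, 8335 and 3496 UMIs. In the B-like clusters 7 and 8 it was found in 52.7% and 33.7%, at 858 and 4871 UMIs. Trbc2, of the β chain, was found in 97.2%, 96.5% and 96.1% of the same 3 clusters and in 88.8% and 100% of clusters 5 and 9, so these shares do not settle the class of clusters 2, 3 and 10. B-like clusters made up 15.3% (13.0 to 17.8) of the kept cells of adult spleen, 4.37% (2.97 to 6.18) of pup spleen and 4.49% (1.96 to 8.66) of adult meninges. In pup meninges they held 0 of 110 cells, which allows a share of up to 2.73%, or 3.30% by the exact interval.

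The receptor genes separated the tissues. Tcrg-V6 and Trdv4 encode the γ and δ variable segments that pair in a fetal wave of IL-17-producing γδ T cells. Tcrg-V6 made up 30.5% (19.2 to 43.9) of the 59 γ variable gene UMIs of adult meninges and 38.8% (25.2 to 53.8) of the 49 of pup meninges. Counted per cell it was found in 36.4% (16 of 44) and 59.3% (16 of 27) of the cells with a γ variable gene UMI. In spleen its share was 1.12% (0.0284 to 6.10) of 89 UMIs in adults and 1.01% (0.209 to 2.92) of 297 in pups. Trdv4 made up 84.6% (76.8 to 90.6) of the δ variable gene UMIs of adult meninges, 77.4% (63.8 to 87.7) of pup meninges, 25% (17.2 to 34.3) of pup spleen and 1.11% (0.0281 to 6.04) of adult spleen. Tcrg-V1 led the γ variable genes of adult spleen with 87.6% (79.0 to 93.7) and of pup spleen with 87.9% (83.6 to 91.4), against 49.2% (35.9 to 62.5) in adult meninges and 46.9% (32.5 to 61.7) in pup meninges. In the GRCm38 (mm10) annotation, Tcrg-V6 lies on chromosome 13, 19190356 to 19190929, and Trdv4 on chromosome 14, 54074905 to 54075515.

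**Figure D1:**
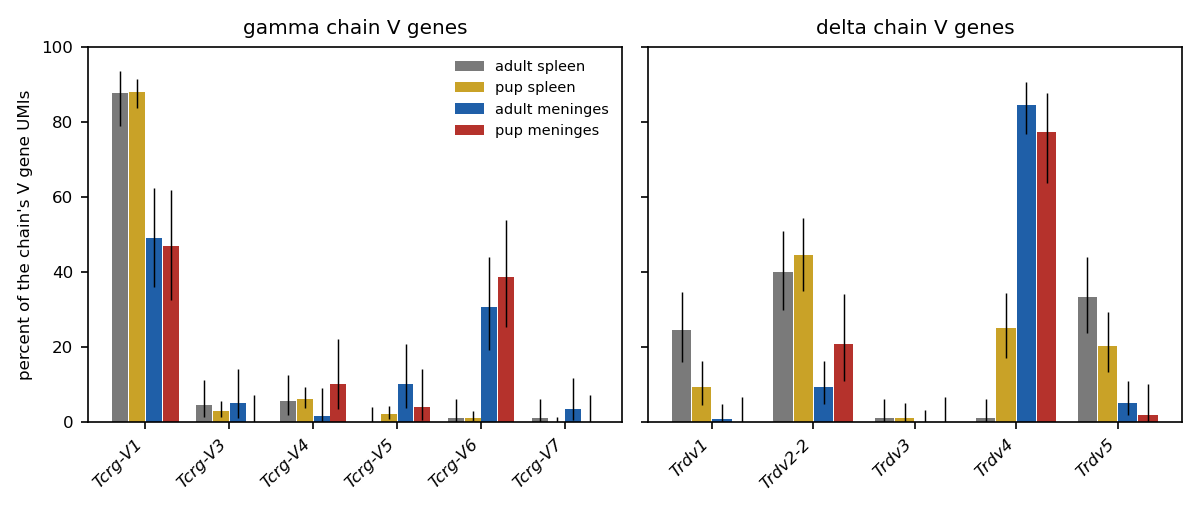
Share of each γ (left) and δ (right) variable gene among the variable gene UMIs of its chain, in percent, for the 4 libraries; bars are single libraries and lines are exact 95% counting intervals. Trdv4 reaches 84.6% in adult meninges and 77.4% in pup meninges, against 1.11% in adult spleen.

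The first comparison asks how γδ T cells of the adult meninges differ from those of the adult spleen. Genes of the IL-17-producing programme were far higher in the meninges: 21 of 22 measured members of the type 17 list were at least 2-fold higher and 1 lay between, with a median log2 ratio of 4.30 (4.00 to 4.61). That median lay at percentile 100 of 10000 random lists matched on expression. Il23r and Il1r1, receptors for the cytokines that drive IL-17 release, were 90.1-fold higher (15.5 to 3624) and at least 30.6-fold higher (interval from 24.1), with Il23r at 59.8 against 0.663 CPM (UMIs scaled to the library total). Il17a was seen as 1 against 0 UMIs and Il17f in neither library, so no ratio was computed for these 2 cytokines at this depth.

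Further members of the type 17 list had large ratios. Cd163l1, a scavenger receptor of γδ T cells, was 103-fold higher (61.0 to 189), Ltb4r1, a receptor for leukotriene B4, 414-fold higher (73.6 to 16408), and Tmem176b 33.4-fold higher (25.1 to 45.5). The chemokine receptor Ccr2 was 20.9-fold higher. Among the other genes with the highest ratios were Trdv4 (165-fold higher, 29.0 to 6589), Ly6g5b (184-fold higher, 50.2 to 1525), Krt83 (at least 115-fold higher, interval from 92.8), Npl (at least 31.7-fold higher, interval from 24.96), Dkkl1 (143-fold higher, 25.1 to 5732) and Rln3 (137-fold higher, 23.9 to 5469). On the same genome build, Il17a lies on chromosome 1, 20730905 to 20734496, Il17f on chromosome 1, 20777146 to 20790617, Il23r on chromosome 6, 67422932 to 67491855, Il1r1 on chromosome 1, 40225080 to 40317257 and Cd163l1 on chromosome 7, 140218267 to 140231145.

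Genes of naive and recirculating lymphocytes were lower in adult meninges, with 13 of 15 members at least 2-fold lower, 2 between and a median log2 ratio of -2.28 (-2.78 to -2.09). Klf2, which maintains the recirculating state, was 9.18-fold lower (7.44 to 11.4), and its target S1pr1, the receptor for egress into lymph and blood, was 4.34-fold lower (3.02 to 6.40). Ccr7, which guides cells into lymph nodes, was 12.0-fold lower (5.94 to 28.2), and Dapl1 28.9-fold lower (13.1 to 79.3). In the type 1 list, of IFN-γ-producing and cytotoxic cells, 6 of 24 members were at least 2-fold lower, 4 higher and 14 between. Cd27 was 3.04-fold lower (2.48 to 3.75), Gzmm 10.6-fold lower (3.43 to 53.0) and Cd7 5.15-fold lower. Ifng was 1.46-fold lower (0.798 to 2.80) and Tbx21 1.41-fold lower (0.915 to 2.22), and both intervals included no difference. Gzmb was 4.56-fold higher (2.47 to 8.87), from 5 meningeal and 9 spleen cells with 75.6% of the meningeal UMIs in 1 cell, Fasl 2.81-fold higher and Cxcr3 2.02-fold higher. Gzma was 2.28-fold higher, from 2 meningeal and 17 spleen cells, and its log2 ratio was -5.11 without clusters 2, 3 and 10.

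Of the genes linked to retention in tissue, 9 of 17 were at least 2-fold higher in adult meninges, 1 lower and 7 between, with a median log2 ratio of 1.05 (0.83 to 1.52). The number higher was 8 with TMM factors, 7 of 16 with equal weight per cell and, at the lowest, 6 of 11 with at least 50 UMIs per member. Cxcr6, a chemokine receptor of tissue-resident T cells on chromosome 9, 123806475 to 123811760, was 12.5-fold higher (10.7 to 14.8), at 1413 against 113 CPM. Crem was 6.36-fold higher and Gpr183 4.17-fold higher, while Nr4a1 was 5.39-fold lower. The percentiles among random lists were 0 for the naive, 0 for the type 1 and 100 for the residence list. Of the 8 measured receptors for neural and adrenal signals, 4 were at least 2-fold higher and 4 between. Their median log2 ratio was 1.10 (0.77 to 1.84), but it turned slightly negative with members of 1 UMI or more. Ramp1, a co-receptor for the neuropeptide CGRP, was 10.3-fold higher (8.32 to 12.8), Ramp3 10.1-fold higher (5.47 to 20.5), and Nr3c1, the glucocorticoid receptor, 3.07-fold higher (2.15 to 4.42). Adrb1, a β-adrenergic receptor, was seen as 14 against 0 UMIs, at least 7.79-fold higher (interval from 5.53).

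Smaller shifts ran through other lists. In the interferon response list 4 of 20 members were at least 2-fold higher, 1 at least 2-fold lower and 15 between, with a median log2 ratio of 0.73 (0.52 to 0.87). Within cluster 1 alone that median was -0.032. Bst2 was 2.84-fold higher, Ifit3 3.34-fold higher and Ifi27l2a 4.83-fold lower. Chemotactic receptors went both ways, with 6 of 14 at least 2-fold higher and 5 lower. Among cytokines, 4 of 14 were higher and 2 lower, with Csf2 19.5-fold higher (6.14 to 98.9), Tnf 5.72-fold higher and Ccl5 2.44-fold lower. Activation and checkpoint genes split into 4 higher and 4 lower of 13, with Icos 11.8-fold higher, Il2ra 8.90-fold higher and Cd28 3.77-fold lower. Few members passed 2-fold in the glycolysis list (1 higher of 18), the lipid list (2 higher and 1 lower of 10), the stress list (2 and 2 of 18), the cell cycle list (0 and 1 of 9) and the sex-linked list (0 and 1 of 4). The fetal list had 3 higher and 3 lower of 10, and the receptor gene list 3 and 2 of 14.

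The B cell gene Cd79a and 2 genes of MHC class II were also lower in adult meninges. Cd79a was at least 7.79-fold lower (interval from 6.04), H2-Aa 44.4-fold lower (7.72 to 1775) and H2-Eb1 33.6-fold lower (5.78 to 1349), and the B cell markers together stood at 272 CPM against 675. Some other classes had higher values, among them monocyte or macrophage markers at 297 CPM against 147, plasma cell markers at 228 against 61.7 and NK cell markers at 309.8 against 176. Dtx1 was 17.8-fold lower (8.90 to 41.8), Slamf6 14.6-fold lower (7.27 to 34.3), Cd8b1 12.6-fold lower (5.62 to 34.9) and Car2 22.6-fold lower (7.53 to 111). The all-gene median log2 ratio was 0.14 here, 0.14 between the pup tissues, -0.10 for age in meninges and -0.094 for age in spleen, and TMM factors moved these to -0.063, -0.039, 0.00058 and -0.021. Depth per cell was far lower in adult spleen: 395 of its T cells had under 1000 UMIs, against 2 in adult meninges.

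**Figure D2:**
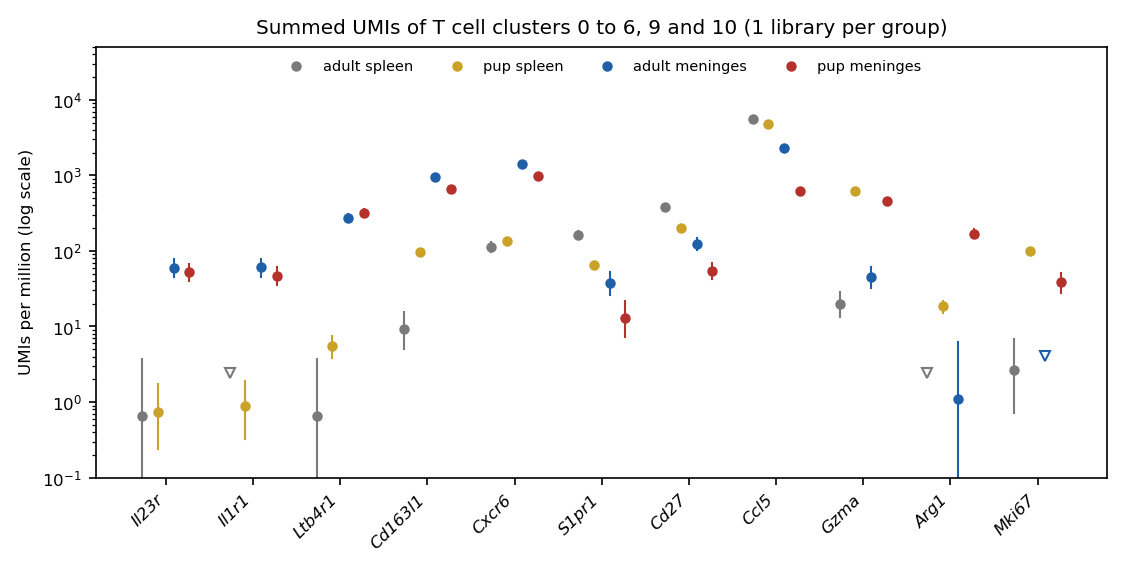
CPM (log scale) of 11 genes in the T cell clusters of the 4 libraries; points are single libraries, lines are 95% counting intervals that stop at the lower axis limit of 0.1, and open triangles mark 0 UMIs at the upper bound of the interval. Il23r, Il1r1 and Ltb4r1 stand higher in both meningeal libraries than in both spleens, and S1pr1 and Cd27 lower.

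The second comparison asks the same of pups. The type 17 list was again higher in meninges, with 21 of 23 members at least 2-fold higher, 1 lower and 1 between, and a median log2 ratio of 4.56 (4.33 to 4.77). The percentiles among random lists were 100 for this list, 0 for the type 1 and 0 for the naive list. Il23r was 72.1-fold higher (29.3 to 230.0), Il1r1 53.2-fold higher (22.9 to 151) and Ltb4r1 58.9-fold higher (42.0 to 85.0). The cytokine genes were seen in pup meninges and not in pup spleen, with Il17a at 6 against 0 UMIs (at least 11.8-fold higher, interval from 6.96), Il17f at 4 against 0 UMIs (at least 7.88-fold higher, interval from 3.90) and Il22 at 16 against 0 UMIs (at least 31.5-fold higher, interval from 22.8). The Il17a UMIs lay in 3 cells and the Il17f UMIs in 2. The member that went the other way was 5830411N06Rik, 2.16-fold lower (1.05 to 5.13).

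The highest ratios outside the receptors above were those of Kcnk1 (260.0-fold higher, 69.9 to 2181), Prr29 (331-fold higher, 57.0 to 13303), Hacd4 (313-fold higher, 53.8 to 12602), Ppp1r14c (159.6-fold higher, 52.7 to 789.9), Slc15a3 (124-fold higher, 40.6 to 618), Npl (99.0-fold higher, 48.8 to 234), Serinc2 (at least 84.7-fold higher, interval from 66.0) and Pram1 (at least 76.8-fold higher, interval from 59.6). Type 1 genes were lower in pup meninges, with 15 of 24 at least 2-fold lower and 9 between (median log2 ratio -1.11, -1.39 to -0.98). Ccl5, a chemokine of cytotoxic lymphocytes, was 7.72-fold lower (7.17 to 8.32), Cd27 3.70-fold lower (2.87 to 4.84) and Klrd1 4.89-fold lower. Ifng was 1.70-fold lower (1.14 to 2.62) and Tbx21 1.53-fold lower (1.07 to 2.27). Naive and recirculating genes were lower too, with 11 of 15 at least 2-fold lower, 1 higher and 3 between, or 7 lower of 14 without clusters 2, 3 and 10. S1pr1 was 5.05-fold lower (3.03 to 9.11), whereas Il7r, the receptor for IL-7, was 2.32-fold higher.

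Residence genes of pups went both ways, with 7 of 18 at least 2-fold higher, 3 lower and 8 between. Cxcr6 was 7.09-fold higher (6.49 to 7.74) and Gpr183 6.69-fold higher, while Itga1 was 2.54-fold lower. Pdcd1, the gene of the inhibitory receptor PD-1, was 26.8-fold higher (20.7 to 35.2), within an activation list of 6 higher and 3 lower of 15. Ccr10, a chemokine receptor for skin and mucosal ligands, was 16.99-fold higher (11.3 to 26.3), within 8 higher and 4 lower of 17 chemotactic receptors. Ramp1 was 7.01-fold higher and Ramp3 12.2-fold higher, and 4 of 9 receptors for neural signals were higher and 2 lower. In the interferon response list 1 of 20 members were at least 2-fold higher, 8 at least 2-fold lower and 11 between, with a median log2 ratio of -0.58 (-0.78 to -0.35); Ifi27l2a was 7.99-fold lower and Rtp4 3.10-fold lower. Cytokines split evenly, with 5 higher and 5 lower of 16. The stress list had 5 higher and 1 lower of 17, with Fos 6.58-fold higher, and the fetal list 3 and 6 of 12.

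Some of the genes lowest in pup meninges marked few cells of pup spleen. Elane (at least 35.9-fold lower, interval from 29.1), Ctsg (at least 29.0-fold lower, interval from 23.5), Mpo (at least 24.6-fold lower, interval from 19.9), Prtn3 (at least 23.2-fold lower, interval from 18.8) and S100a8 (at least 14.4-fold lower, interval from 11.6), genes of granulocyte precursors, had 2228 of their 2254 UMIs in 3 cells, and Ms4a3 (at least 8.12-fold lower, interval from 6.52) had 96.5% of its UMIs in 1 cell. Cd8b1 (12.8-fold lower, 6.94 to 26.9), Nsg2 (22.9-fold lower, 6.29 to 190.3) and Mxd3 (36.5-fold lower, 6.49 to 1450.2) were spread over 141, 182 and 76 pup spleen cells. In the T cell clusters, erythroid markers summed to 27.0 CPM in pup meninges against 2001 in pup spleen, and progenitor markers to 28.7 against 224, the same direction as the type 1 and naive lists and the cell cycle count below. NK cell markers (277 against 441) and B cell markers (144 against 421) went the same way, and cluster 3 held 5 pup meningeal and 145 pup spleen cells. Among classes that went the other way were monocyte or macrophage markers (219 against 138) and plasma cell markers (158 against 50.3). Cell cycle genes were at least 2-fold lower for 11 of 20, with Mki67 2.61-fold lower (1.92 to 3.62). That count was 1 of 20 once the shallow cluster 11, which holds 33 pup meningeal cells and is led by cycling genes, was added back, so no direction is given for cycling between the pup tissues. The receptor gene list had 3 higher and 4 lower of 15, and the lipid, glycolysis and sex-linked lists 1, 2 and 0 members higher and 0, 1 and 1 lower of 11, 18 and 6.

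**Figure D3:**
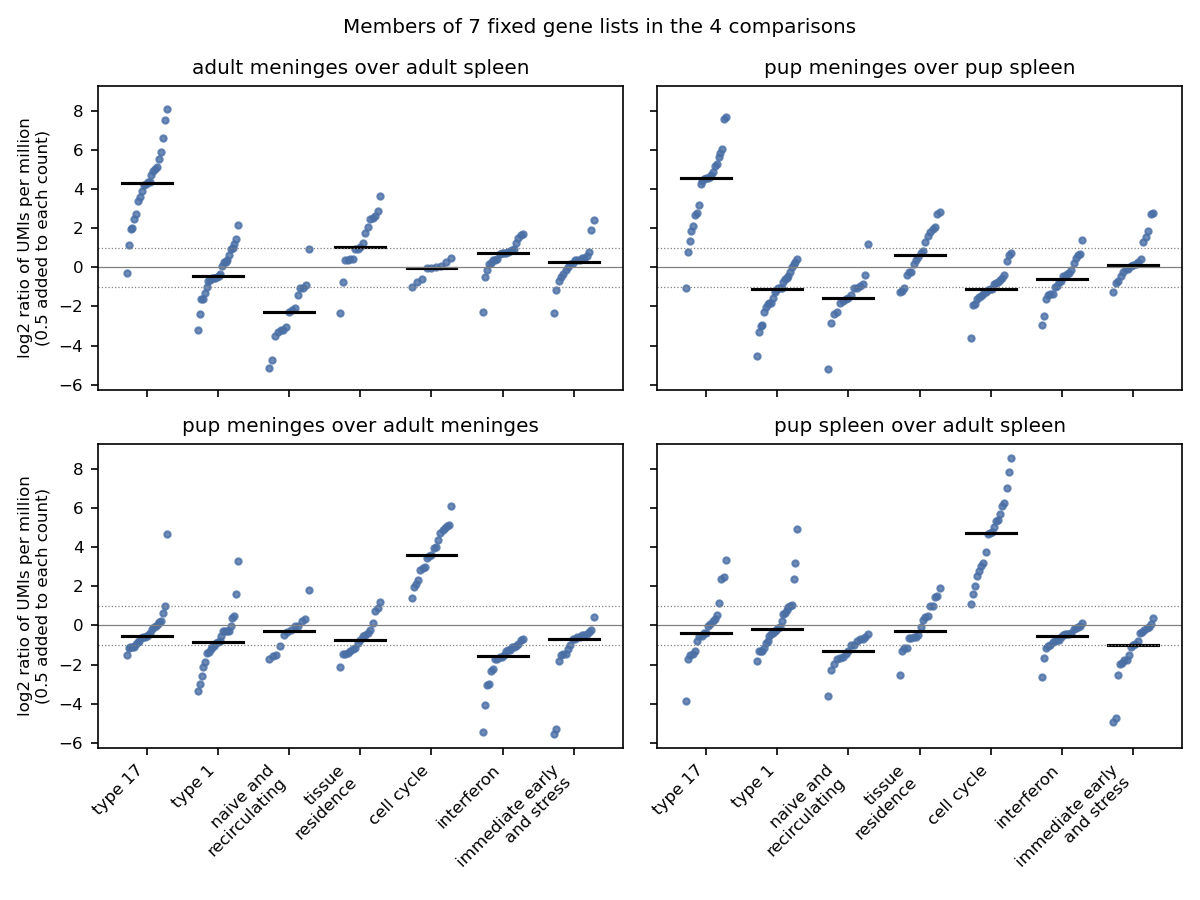
Log2 ratio of CPM (0.5 added to each count) for each measured member of 7 gene lists in the 4 comparisons; points are genes in order of their ratio, bars are list medians, and dotted lines mark a 2-fold difference. Type 17 genes separate meninges from spleen at both ages, and cell cycle genes separate pups from adults in both tissues.

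The third comparison asks how meningeal γδ T cells of pups differ from those of adults. Cell cycle genes were higher in pups, with 19 of 19 measured members at least 2-fold higher and a median log2 ratio of 3.62 (3.21 to 4.34), or 3.53 with genes unseen in adults placed at their bound. Mki67, a marker of proliferating cells, was at least 11.5-fold higher (interval from 8.99), Rrm2, a subunit of the enzyme that makes deoxynucleotides, 52.7-fold higher (9.13 to 2111), and Birc5 33.0-fold higher (8.86 to 277). At least 2 UMIs over 5 cycling genes were found in 28 of 77 pup cells and 1 of 169 adult cells, at median depths of 13813 and 5179 UMIs. Thinned to 500 UMIs per cell, Mki67 was found in 0 of 77 pup and 0 of 168 adult cells. Without the cycling cells 3 of 8 measured members were at least 2-fold higher. Interferon response genes were lower in pups, with 17 of 20 at least 2-fold lower, 3 between and a median log2 ratio of -1.55 (-1.76 to -1.31). The percentiles among random lists were 100 for the cell cycle, 0 for the interferon, 0 for the type 1 and 0.0200 for the stress list. Ifit3 was 20.4-fold lower (5.19 to 175), Isg15, a ubiquitin-like protein induced by interferon, 8.11-fold lower (4.76 to 14.7), and Ly6a 5.09-fold lower (3.78 to 6.95). Markers of dendritic cells (107 against 294 CPM) and of B cells (144 against 272) were lower in pups as well.

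Arg1, the gene of arginase on chromosome 10, 24915221 to 24927484, was 153-fold higher (27.2 to 6085) in pup meninges, at 169.6 against 1.11 CPM. Its UMIs lay in 33 of the 77 pup cells, with 24.1% of them in 3 cells. In pup spleen 34 of 645 T cells had Arg1, at 18.4 CPM and a median depth of 8773 UMIs, against 0 of 30 B-like cells at 6048.5. Ccr10 was 24.1-fold higher (7.99 to 119) and Nrgn 29.9-fold higher (9.97 to 147). The other genes with the highest ratios were Tk1 (at least 19.4-fold higher, interval from 15.4), Pclaf (32.4-fold higher, 12.4 to 120.4), Ccnb2 (50.3-fold higher, 8.71 to 2018) and Ube2c (36.9-fold higher, 9.95 to 309.5), all of the cell cycle, and 69.1% of the Ube2c UMIs lay in 1 cell. Among the lowest were Camk2n1 (153-fold lower, 26.9 to 6079), Klra1 (26.7-fold lower, 6.95 to 228), Dkk3 (17.8-fold lower, 4.49 to 154), Zbtb20 (9.70-fold lower, 4.62 to 23.5) and Tsc22d3, a gene induced by glucocorticoids (8.27-fold lower, 5.14 to 14.0). Olfr655 was 52.2-fold lower (8.85 to 2109.7), with all its adult UMIs in 1 cell. Arg1 and Ccr10 were among the 10 leading genes of cluster 9, which held 58 pup and 3 adult meningeal cells. Camk2n1 was among those of cluster 5, with 4 pup and 115 adult meningeal cells. A different mixture of clusters thus cannot be told apart for Arg1, Ccr10 and Camk2n1.

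The type 17 programme was present at both ages, with 16 of 23 members between, 5 at least 2-fold lower in pups and 2 higher (median log2 ratio -0.53, -0.63 to -0.30). Cxcr6 was 1.46-fold lower (1.34 to 1.58) in pups, while the intervals of Il23r, Il1r1, Ifng and Tbx21 included no difference. Il17a was seen as 6 against 1 UMIs, a ratio of 4.72 (0.572 to 217), and Il22 as 16 against 0 UMIs (at least 4.19-fold higher, interval from 3.03). Il18r1, a subunit of the IL-18 receptor, was 2.86-fold lower (2.34 to 3.51). Type 1 genes were lower in pups, with 10 of 23 at least 2-fold lower, 2 higher and 11 between, or 16 of 23 lower without cycling cells, 8 without doublets and 7 without clusters 2, 3 and 10. Ly6c2 was 5.99-fold lower (5.13 to 7.03), Klrc2 10.7-fold lower (4.89 to 27.8), Ccl5 3.69-fold lower and Cd27, on chromosome 6, 125232622 to 125237010, 2.28-fold lower (1.66 to 3.16). Gzma, a granzyme, was 10.1-fold higher (7.33 to 14.2), from 10 pup and 2 adult cells. Cd8a was 3.14-fold higher (1.60 to 6.75), from 6 pup and 2 adult cells, so both ratios rest on few cells, and without cycling cells the log2 ratio of Cd8a was -1.10. S1pr1 was 2.88-fold lower (1.53 to 5.70) in pups, within a naive list of 4 lower and 1 higher of 12. Of the adult UMIs, 29 of 34 for S1pr1, 63 of 113 for Cd27 and 29 of 42 for Klra1 lay in cluster 1. That cluster held 31 adult and 0 pup meningeal cells, so a different mixture of clusters cannot be told apart for these genes.

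Immediate early and stress genes were lower in pup meninges for 8 of 18 members with 10 between (median log2 ratio -0.70, -0.97 to -0.61), and for 5 of 16 without clusters 2, 3 and 10. Hspa1a was at least 6.36-fold lower (interval from 4.56), Dnajb1 2.87-fold lower and Btg2 3.50-fold lower. Residence genes were lower for 7 of 17 and higher for 1, with Cd69 2.72-fold lower and Odc1, which starts polyamine synthesis from ornithine, 2.28-fold higher. Nr3c1 was 2.85-fold lower (1.96 to 4.23), and 3 of 7 receptors for neural signals were lower. In the glycolysis list 4 of 18 were higher and 1 lower, with Tpi1 2.69-fold higher, Gapdh 2.52-fold higher and Pdk1 3.25-fold lower. In the lipid list 2 of 10 were higher, with Fabp5 3.05-fold higher. The cytokine list had 3 higher and 4 lower of 15, the chemotactic receptors 2 and 2 of 15, the activation list 0 and 1 of 10, the fetal list 3 and 1 of 9, and the receptor gene list 0 and 2 of 11. Xist, transcribed from the inactive X chromosome of female cells, was seen as 358 against 0 UMIs, and the Y-linked Ddx3y was 2.92-fold lower (1.83 to 4.78) in pups.

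The fourth comparison sets pup spleen against adult spleen. Cell cycle genes were higher in pups for 20 of 20 members, with a median log2 ratio of 4.76 (4.26 to 5.33), or 4.71 with unseen genes at their bound. Mki67 was 37.6-fold higher (14.6 to 138), Top2a, which untangles replicated DNA, 44.4-fold higher (21.5 to 111), Birc5 85.4-fold higher (33.3 to 314), Ube2c 347-fold higher (62.2 to 13709), Cdca3 78.3-fold higher (21.6 to 648) and Ccnb2 at least 63.6-fold higher (interval from 51.6). Among random lists the cell cycle list stood at percentile 100, the stress list at 0 and the naive list at 0. Cycling cells numbered 205 of 645 in pups and 4 of 749 in adults, at median depths of 8773 and 910 UMIs, which raises the number in pups. Thinned to 500 UMIs per cell, Mki67 was found in 4.55% (3.06 to 6.46) of pup and 0.178% (0.00450 to 0.986) of adult spleen cells. In pup spleen 0 of 30 B-like cells had it after thinning, which allows up to 10%, or 11.6% by the exact interval. The thinned pup share thus cannot be told from background on so few B-like cells. In UMIs summed without thinning, Mki67 stood at 7.98 CPM (2 UMIs) in these 30 B-like cells. In the T cell clusters of pup spleen it stood at 99.8 CPM (92.4 to 107.6). Without the cycling cells 11 of 17 members were at least 2-fold higher. Gzma was 31.2-fold higher (21.9 to 46.4), Gzmb 9.50-fold higher (5.72 to 17.1), Cd8a 5.20-fold higher (3.54 to 7.96) and Ccl4 11.3-fold higher (6.58 to 21.4). The type 1 list as a whole had 4 higher, 5 lower and 15 between of 24, with Ifng 1.54-fold higher (1.10 to 2.22) and Tbx21 1.10-fold lower (0.840 to 1.43).

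Immediate early and stress genes were lower in pup spleen, with 10 of 19 at least 2-fold lower, 9 between and a median log2 ratio of -1.004 (-1.29 to -0.76). The heat shock genes Hspa1a and Hspa1b were 32.7-fold lower (15.5 to 79.2) and 27.6-fold lower (13.0 to 67.5). The same list had a median log2 ratio of -0.999 (-1.47 to -0.61) in the B-like cells of the 2 spleens, and of -0.84 in cluster 8, the only B-like cluster with cells of both. In T cell cluster 1 its median was -0.17, with 4 of 16 members at least 2-fold lower. Naive and recirculating genes were lower in pups for 8 of 15 with 7 between (median -1.31, -1.48 to -1.09), and for 13 without clusters 2, 3 and 10 or 5 with each cell given equal weight. Dapl1 was 12.2-fold lower (9.72 to 15.3), S1pr1 2.47-fold lower (2.11 to 2.90) and Cd27 1.88-fold lower (1.70 to 2.07). Other genes with the lowest ratios were Hes1, a target of Notch signalling (21.3-fold lower, 10.98 to 45.3), Tsc22d3 (8.36-fold lower, 6.77 to 10.4), Casp1 (10.8-fold lower, 6.51 to 18.4), Gpr55 (15.2-fold lower, 7.57 to 32.9), Prdm16 (11.6-fold lower, 6.88 to 20.2), Metrnl (11.4-fold lower, 5.86 to 23.7) and Rsrp1 (6.19-fold lower, 5.67 to 6.77). Of these, Hes1, Casp1, Gpr55, Prdm16 and Metrnl were among the 10 leading genes of cluster 10, which held 40 adult and 11 pup spleen cells. A different mixture of clusters was not tested for them.

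Type 17 genes were low in both spleens and split between the ages, with 4 of 19 at least 2-fold higher in pups, 5 lower and 10 between. Cd163l1 was 10.4-fold higher (6.16 to 19.2) and Ccr2 5.22-fold higher (3.48 to 8.22) in pups, while Ccr6 was 16.5-fold lower (4.36 to 92.2). Il17a and Il17f were unseen in both. Cxcr6 was 1.21-fold higher (1.03 to 1.44), within a residence list of 5 higher and 4 lower of 18. Icos was 3.60-fold higher and Pdcd1 5.27-fold lower, within an activation list of 1 higher and 6 lower of 15. In the fetal list 5 of 13 were higher and 4 lower, with Igf2bp3, an RNA-binding protein of fetal cells, 5.52-fold higher (3.24 to 10.2). Interferon genes were lower for 4 of 20 (median -0.53, -0.69 to -0.42). The chemotactic receptors had 4 higher and 7 lower of 17, the receptors for neural signals 2 and 4 of 9, the receptor gene list 1 and 5 of 15, and the cytokines 2 and 2 of 15. Glycolysis genes had 2 higher and 2 lower of 18, and lipid genes 1 and 1 of 11.

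Markers of other classes also differed between the spleens. Erythroid markers together reached 2001 CPM in the T cell clusters of pups against 85.6 in adults, and progenitor markers 224 against 11.3. NK cell markers stood at 441 CPM in pups against 176, the same direction as Gzma and Gzmb, and cluster 3, led by Gzmb and Gzma, held 145 pup and 7 adult spleen cells. Cd8a stood at 206 CPM in cluster 2 against 29.4 in cluster 3, and cluster 2 held 204 pup and 13 adult spleen cells. Elane (at least 47.0-fold higher, interval from 38.1), Ctsg (at least 38.1-fold higher, interval from 30.9), Mpo (at least 32.3-fold higher, interval from 26.1) and Prtn3 (at least 30.5-fold higher, interval from 24.7) were among the highest ratios, each with 97.8% to 99.4% of its UMIs in 1 cell. Xist was seen as 2826 against 0 UMIs, and Ddx3y was 2.87-fold lower (2.14 to 3.84) in pups.

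Shares of cells with a transcript repeated the tissue difference. After each cell was thinned to 500 UMIs, Cxcr6 was found in 50.6% (42.8 to 58.4) of adult meningeal cells, 41.6% (30.4 to 53.4) of pup meningeal cells, 7.28% (5.28 to 9.75) of adult spleen cells and 7.21% (5.33 to 9.50) of pup spleen cells. Tmem176b was found in 44.6% (37.0 to 52.5), 26.0% (16.6 to 37.2), 0.888% (0.289 to 2.06) and 0.470% (0.0971 to 1.37) in the same order. Without thinning the Cxcr6 shares were 89.3%, 93.5%, 14.2% and 39.5%, at medians of 5179, 13813, 910 and 8773 UMIs per cell. In the B-like cells of adult spleen, used as a measure of background, the thinned Cxcr6 share was 1.69% (0.206 to 5.99) at a median of 1858 UMIs before thinning, against 1313 in the T cells of that library. Tmem176b was found in 0 of 118 cells, which allows a share of up to 2.54%, or 3.08% by the exact interval, so its share in adult spleen T cells cannot be told from background. Without thinning 8.09% of 136 adult spleen B-like cells had Cxcr6, at a median of 1334 UMIs. Adult meninges had 8 B-like cells, of which 3 had Cxcr6 without thinning (37.5%, 8.52 to 75.5) and 0 after it. After thinning 2 had Tmem176b (25%, 3.19 to 65.1, at a median of 5135 UMIs), so part of the Tmem176b and unthinned Cxcr6 shares in that library can be background. In pup spleen 0 of 30 B-like cells had Cxcr6 or Tmem176b after thinning, which allows a share of up to 10%, or 11.6% by the exact interval. The thinned pup spleen shares of both genes thus cannot be told from background, and pup meninges had no B-like cells to measure it. In UMIs summed without thinning, Cxcr6 stood at 31.9 CPM (8 UMIs) in the pup spleen B-like cells. In the T cell clusters of that library it stood at 137 CPM (128 to 146). Thinning left out 186 adult spleen cells, 7 pup spleen cells, 1 adult meningeal cell and 0 pup meningeal cells.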

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

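In this part the values of clusters 1 and 8 and the rule that the mixture test needs enough cells of both libraries per cluster were chosen after the result was seen. The median log2 ratio of the interferon response list, meninges over spleen, had opposite signs at the 2 ages: 0.73 (0.52 to 0.87) in adults, with 4 of 20 members at least 2-fold higher, and -0.58 (-0.78 to -0.35) in pups, with 8 of 20 lower, while 15 and 11 members lay between. The difference between these differences was not tested, as each group is 1 library. In cluster 1 alone (31 meningeal and 175 spleen cells) the adult median was -0.032, with 1 of 19 members higher and 2 lower. The higher adult values in meninges were thus not seen within this cluster. For the lower values of pup against adult meninges, a few cells with a high share of interferon list UMIs are argued against. Without the 5% of cells with the highest share the median was -1.22 (-1.48 to -0.996), with 11 of 18 genes at least 2-fold lower. Cells were ranked by the share of their UMIs from this list. Deep cells with many such UMIs need not have been removed, so the test does not cover them. A different mixture of clusters cannot be told apart: between the largest cluster of each library (cluster 9, 58 pup cells, and cluster 5, 115 adult cells) the median was -1.41 (-1.77 to -1.27), but cluster 9 held 3 adult cells and cluster 5 4 pup cells. Age, sex and handling of the single libraries stay open and untested, and in the splenic B-like cluster 8 the pup over adult median was -1.68, a value that RNA of T cells may give there, as the receptor genes stood at -2.14, type 1 genes at -1.48 and naive genes at -1.57.

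Gzmb was higher in meninges than in spleen in adults, at a ratio of 4.56 (2.47 to 8.87), and lower in pups, at 0.479 (0.354 to 0.636), but 75.6% of the adult meningeal UMIs lay in 1 of 5 cells, so the adult ratio rests mostly on that cell. Cxcr5 was higher in pups than in adults in meninges, at a ratio of 12.6 (1.95 to 527) from 16 against 1 UMIs in 11 and 1 cells, and lower in pups in spleen, at 0.281 (0.135 to 0.594). Itga1 went the other way, with pup over adult ratios of 0.210 (0.0506 to 0.658) in meninges and 4.44 (1.45 to 22.1) in spleen. These 3 genes stood out because their summed counts passed 2-fold in opposite directions in the 2 comparisons, and the difference between the 2 ratios was not tested. Cells outside the T cell clusters stood out because none of the 4 comparisons summed them, which left them to the background shares and the tests on B-like cells, and their shares were not tested between libraries. B-like clusters held 15.3% (13.0 to 17.8) of kept cells in adult spleen, 4.37% (2.97 to 6.18) in pup spleen and 4.49% (1.96 to 8.66) in adult meninges. The unnamed cluster held 0.450% (0.123 to 1.15) in adult spleen, 1.75% (0.906 to 3.03) in pup spleen, 0.562% (0.0142 to 3.09, 1 cell) in adult meninges and 30% (21.6 to 39.5) in pup meninges. The nearest class of this cluster was γδ T cells, so its cells need not be of another type.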

How the results depend on the processing

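No paired analysis was possible because the labels pair no animals across the 4 pooled libraries. The settings without clusters 2, 3 and 10, with cluster 11 added back, without granulocyte precursor cells, with a minimum of 1000 UMIs per cell and thinned to 2000 UMIs were chosen after seeing the data. Member counts stayed within 1.5 times the reported count in 195 of 210 values. The type 17 count ranged from 19 to 22 in adults and 19 to 23 in pups, and the interferon count for age in meninges from 13 to 18. List medians were within their counting interval in 855 of 960 values, outside it in 91 of 960 and reversed in 14 of 960. For gene ratios these numbers were 5679 of 6086, 387 of 6086 and 20 of 6086. The settings of at least 1 and at least 50 UMIs per list member cannot change a gene ratio, yet their values are counted here. Leaving out granulocyte precursor cells changed pup spleen only, so comparisons without that library could not change under this setting. B-like shares stayed within their interval in 12 of 12 values, V gene shares in 47 of 48 and shares of cells in 261 of 592. Il17a and Il17f had at most 6 UMIs in a library. Except where a setting removes or adds the cells concerned, the cause of the shifts below was not tested.

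Values are log2 ratios unless called counts. Between the pup tissues, the cytokine median was -0.0038 with TMM factors and -0.027 with equal weight per cell. The stress median was -0.042 with TMM factors, -0.031 with median of ratios and -0.066 with equal weight. Cell cycle members at least 2-fold lower numbered 1 with all kept cells (median 0.0030, Birc5 0.012) and 1 with all barcodes (median 0.055, Birc5 0.029, Cd81 1.25). They numbered 1 with cluster 11 added back and 17 without clusters 2, 3 and 10, where the naive count was 7, Pcna -0.10 and Btg2 0.033. Without cycling cells they numbered 2 (median 0.33), with Mki67 at 0.74, Nusap1 2.10, Ccna2 1.84, Birc5 0.34, Tnfrsf4 -1.12, Cxcr3 0.10 and Xist 0.095. With at least 50 UMIs per member the chemotactic receptor median was -0.00080.

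For age in meninges, the stress count was 5 with equal weight, 5 with at least 50 UMIs, 5 without cycling cells and 5 without clusters 2, 3 and 10, where Cd40lg was 0.82. Without cycling cells the type 1 count was 16, the cell cycle count 3, Cd8a -1.10, Igfbp4 -0.96 and Ccl4 -1.70. For age in spleen, equal weight gave a type 1 median of 0.021, a naive count of 5, Zbtb16 -0.18 and Ccl5 0.38. All barcodes gave a type 1 median of 0.029. Without cycling cells the cell cycle count was 11 and Ccl5 0.18. The neural receptor median was 0.52 with at least 50 UMIs and 0.0035 without clusters 2, 3 and 10, where the naive count was 13. Between the adult tissues, the neural receptor median was -0.050 with members of 1 UMI or more, and Gzma -5.11 without clusters 2, 3 and 10.

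The share of cells with Cxcr6 depends on depth. In adult meninges, pup meninges, adult spleen and pup spleen it was 89.3%, 93.5%, 14.2% and 39.5% unthinned, and 85.8%, 89.6%, 4.54% and 23.3% with 2 or more UMIs. Thinned to 1000 UMIs it was 68.3%, 62.3%, 8.19% and 11.4%, and to 2000 UMIs 79.7%, 80%, 16.1% and 18.4%. Counted per cell, Tcrg-V6 was found in 59.3% of the pup meningeal cells with a γ variable gene UMI.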

Other observations

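Within a single cluster the tissues still differed. Cluster 1 held 31 cells of adult meninges and 175 of adult spleen. Here the naive list was at least 2-fold lower in meninges for 8 of 15 members, and type 1 genes were higher for 9 of 21 and lower for 1. The meninges over spleen ratio was 23.5-fold (8.998 to 77.8) for Klra1 and 4.48-fold (3.25 to 6.19) for Klrk1, receptors shared with NK cells. It was 9.16-fold (5.51 to 15.7) for Tyrobp and 9.46-fold (6.69 to 13.6) for Fcer1g, signalling adaptors of such receptors. It was 8.57-fold (5.92 to 12.6) for S100a4, 4.19-fold (2.88 to 6.10) for Cxcr6 and 4.21-fold (3.18 to 5.59) for Xcl1, a chemokine gene. Klf2 had a ratio of 0.344-fold (0.270 to 0.432), Ccr7 of 0.215-fold (0.0848 to 0.455) and Dapl1 of 0.108-fold (0.0392 to 0.239). The type 17 list had 3 higher and 3 lower of 11.

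Immunoglobulin transcripts were found outside the B-like clusters. Ighm stood at 267 CPM in the T cell clusters of adult spleen, 241 in pup spleen, 136 in adult meninges and 87.0 in pup meninges. There were 5.54 Ighm UMIs per Igkc UMI in the T cell clusters of pup spleen against 0.574 in its B-like cells, and 2.30 against 0.271 in adult spleen. Other marker classes were summed over the T cell clusters, here in the order adult spleen, pup spleen, adult meninges and pup meninges. Monocyte or macrophage markers stood at 147, 138, 297 and 219 CPM and NK markers at 176, 441, 309.8 and 277. Dendritic markers stood at 279, 119, 294 and 107 CPM and plasma cell markers at 61.7, 50.3, 228 and 158. Over the 4 libraries, innate lymphoid markers ranged from 49.6 to 149 CPM, endothelial markers from 19.1 to 51.7 CPM, neural or glial markers from 39.0 to 44.3 and fibroblast markers from 0 to 11.1. Neutrophil markers ranged from 0 to 45.5 CPM, mast cell or basophil markers from 0 to 4.35 and platelet markers from 0 to 5.53. αβ T cell markers, which γδ T cells partly share, ranged from 1762 to 2756 CPM, and γδ T cell markers from 5609 to 11483.

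Of the tests that follow, the 2 tests of Arg1 in few cells, the Cst3 values and the values within clusters 1 and 8 were chosen after the result was seen. The stress list had 8 of 18 members at least 2-fold lower in pups in meninges and 10 of 19 in spleen. A few cells with a high share of stress UMIs are argued against, since without the 5% of cells with the highest share the spleen median was -0.95 (-1.20 to -0.70). Cells were ranked by the share of their UMIs from this list. Deep cells with many stress UMIs need not have been removed, so the test does not cover them. Handling or digestion that acted on every cell of the adult libraries stays open, since the splenic B-like cells showed a median of -0.999 (-1.47 to -0.61), with 7 of 14 genes at least 2-fold lower over 30 pup and 136 adult cells, of which 90 lay in cluster 7 with 0 pup cells, and -0.84 with 5 of 12 lower in cluster 8 alone. RNA of T cells in these droplets may add to these values, as T cell receptor genes had a median of -2.14 in the B-like cluster 8. In T cell cluster 1, with 25 pup and 175 adult spleen cells, the stress median was -0.17, with 4 of 16 genes at least 2-fold lower. An effect on every adult cell would also be present there, but no interval was computed for this value. Age and sex stay open and untested.

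For the high Arg1 of pup meninges, cells or RNA of macrophages are argued against, since 8 macrophage genes (Lyz2, C1qa, C1qb, C1qc, Csf1r, Adgre1, Mrc1 and Ms4a7) summed to 0 CPM (0 to 3.21) in the same cells, where Arg1 stood at 169.6 (147 to 195). The wider list of 14 monocyte or macrophage markers summed to 219 CPM, of which Cst3 gave 208, and Cst3 stood at 247 in adult meninges, where Arg1 was 1.11. The 3 cells with most Arg1 held 24.1% (18.3 to 30.7) of 195 UMIs, which is not clear of the bound of 25% set for few cells. That the ratio rests on these cells is argued against, since without them it was 122 (21.5 to 4835). Age, sex and handling stay open and untested. A different mixture of clusters cannot be told apart, as Arg1 was a leading gene of cluster 9, with 58 pup and 3 adult meningeal cells.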
